A study of Mus musculus with 2 samples.

How the data were processed

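Tumour tissue of the mouse mammary gland was the material in both groups, 1 treated with a PD-1 inhibitor by intraperitoneal injection and 1 treated with the same injection plus acupuncture. Per the labels' protocols, total RNA was extracted with a column kit and libraries were built with a SMARTer kit for messenger RNA. The authors deposited raw whole-number read counts per gene symbol, with 1 column per library and no normalization. Genome builds named GRCm39 and mm39 are listed in the submitters' processing notes. The aligner, the counting program, their versions and the strand setting are not given in the sources used here. The table held 35602 gene symbols and 0 lines that name no gene. Total counts were 105728292 with the PD-1 inhibitor alone and 60752043 with acupuncture, a ratio of 1.74. Coordinates are not printed because the reference used here follows another assembly than the authors' counts.

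Library sizes were multiplied by TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.966 with the PD-1 inhibitor alone and 1.04 with acupuncture, and the median log2 ratio over tested genes was then 0.0003. CPM values are counts per 1000000 of these scaled library sizes. Ratios are acupuncture over PD-1 inhibitor alone, with an exact Clopper-Pearson 95% interval from the binomial split of the combined count. A gene was listed as higher or lower when its ratio was at least 2-fold and the interval excluded 1, among the 18687 genes with a combined count of at least 20. All other genes count as between. Log2 ratios carry a prior count of 2, so for genes with few counts they differ from the log2 of the printed fold. Where a library held 0 counts, the fold was taken against a floor of 3 counts per library (0.0294 and 0.0477 CPM) and is given as a lower bound. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per group no test between groups was possible, no p-value was computed, and the counts of genes describe these 2 libraries and not the treatments.

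In advance of the analysis, 44 gene lists of cell types, pathways and sample quality were fixed, with 888 entries. Of these, 21 had no symbol in the table, most of them constant segments of antigen receptors. Each list is summarised by the median log2 ratio of its measured members, a binomial 95% interval of that median over genes, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is no p-value, and genes of 1 list are not independent. Families were also taken by the start of the symbol. No symbol began with mt-, so mitochondrially encoded genes were taken by their RefSeq symbols, a choice made after the symbols were seen, and no symbols of immunoglobulin or T cell receptor variable segments were found.

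Named genes followed a rule. It took the 10 highest and 10 lowest log2 ratios among listed genes with a combined count of at least 100, leaving out clone-type names, receptor segments, pseudogenes and mitochondrial genes. It added the CD genes named by the study with Pdcd1, Cd274 and Ptprc, up to 4 examples per list (the most abundant and the most different members), and the 10 most abundant genes of each library. Some genes that the rule names are not reported here. Granzymes outside this rule were chosen after their values were seen. Other prior counts (0.5 and 5), count minimums (1 and 100), a 4-fold limit, ratios without the interval, means and summed counts, scaling by total counts, by DESeq2 1.42.0 size factors, by upper quartile and by totals without the 10 most abundant genes were tried as alternatives. Thinning the deeper library and scaling to the epithelial list were added after the data were seen.

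The calculation was tested on simulated data with Poisson counts at the real depths, over 18773 genes. Of 50 genes made 4-fold higher and 50 made 3-fold higher, 100% were listed, against 97.8% of 46 genes made 4-fold lower and 93.6% of 47 made 3-fold lower. Of 18580 unchanged genes 0.344% were listed, and 95.5% of intervals held the true ratio. The simulation had no variation between animals and no counting error beyond Poisson. Apart from the genes changed, both libraries had the same expression profile. These rates need not hold for libraries that differ in tissue content. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.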

Results

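Breast tumour tissue from mice given a PD-1 inhibitor by intraperitoneal injection was compared with tumour tissue from mice given the same injection together with acupuncture. PD-1 is the receptor through which its ligand PD-L1 restrains activated T cells. Messenger RNA was sequenced from 1 library per group, so there were no replicates. Differences between these 2 libraries therefore have no replicate check, and every interval given here covers counting error only. The library of the PD-1 inhibitor alone held 105728292 counts and the library with acupuncture held 60752043, with 23519 and 22939 gene symbols above 0. The question put by the design was how adding acupuncture to PD-1 blockade relates to gene expression in the tumour, and the labels single out the CD genes Cd5, Cd4 and Cd8.

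The CD genes singled out by the study, 4 with both chains of CD8 counted, were all higher in the acupuncture library. Cd5, a scavenger-receptor-family protein found on T cells and on some B cells and dendritic cells, was at 1.71 scaled CPM with the PD-1 inhibitor alone and at 7.06 with acupuncture, 4.12-fold higher (95% counting interval 3.45 to 4.93). Cd4, the co-receptor of helper T cells, stood at 2.83 and 13.4 CPM, 4.74-fold higher (4.15 to 5.44). The chains of the CD8 co-receptor of cytotoxic T cells were 7.38-fold higher for Cd8a (6.24 to 8.77) and 15.0-fold higher for Cd8b1 (12.1 to 18.8). The median log2 ratio of these 4 genes was 2.55, at percentile 99.9 of random lists matched on expression. The study itself singled out these genes, possibly from its own results, so their count is not independent evidence of the direction. The receptor targeted by the treatment, Pdcd1, was 1.66-fold higher (1.39 to 1.98), its ligand Cd274 was 1.81-fold higher (1.73 to 1.91) and the pan-leukocyte phosphatase Ptprc was 1.74-fold higher (1.68 to 1.79), all short of a 2-fold difference. With the epithelial list set to a median of 0 they passed it, at log2 ratios of 1.26 for Pdcd1, 1.39 for Cd274 and 1.33 for Ptprc. That scaling was chosen after the data were seen and raises every log2 ratio, so passing the limit under it is no separate evidence.

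Genes of T cells in general were higher to a similar degree. Of the 22 T cell genes measured, 21 were at least 2-fold higher with acupuncture, none was at least 2-fold lower and 1 lay between, with a median log2 ratio of 2.47 (95% binomial interval of the median over genes 2.03 to 2.75, above all 10000 random lists matched on expression) and 1.03 for the log2 ratio of their summed counts, in which Thy1 weighs most. Lck, the kinase that starts T cell receptor signalling, was 4.93-fold higher (4.55 to 5.34), Themis, needed for T cell selection in the thymus, was 16.3-fold higher (11.2 to 24.4), and the signalling adaptor Sh2d1a was 9.10-fold higher (5.81 to 14.9). The exception was Thy1, which fibroblasts also express, at 0.842 times its level with the PD-1 inhibitor alone (0.817 to 0.867). B cell genes stood further apart, with 15 of 16 higher, none lower and a median log2 ratio of 4.67 (3.17 to 6.48), or 4.77 with members at 0 counts set to the floor of 3 counts per library. The B cell receptor components Cd79a and Cd79b were 46.0-fold (35.0 to 61.8) and 33.2-fold (25.9 to 43.3) higher. Complement receptor 2, Cr2, carried by B cells and follicular dendritic cells, was 134-fold higher (67.7 to 312), and the IgM receptor Fcmr, with 0 and 386 counts, was at least 209-fold higher. Of 6 plasma cell genes measured 3 were higher and none lower, among them Jchain, the joining chain of secreted antibody, at 12.8-fold (11.7 to 14.0) and Mzb1 at 13.4-fold (10.1 to 18.1), and the list median was 0.70 (-0.62 to 3.68) at percentile 99.5, whereas its summed counts were lower, at a log2 ratio of -0.20. Sdc1 and Xbp1, which epithelial cells also express, were 1.54-fold and 1.15-fold lower.

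Markers of lymph node, fat and skeletal muscle were higher in the same library as the T and B cell genes. Of 16 genes of lymph node stroma and lymphoid structure, 13 were higher and none lower, with a median log2 ratio of 3.03 (1.19 to 6.68), or 3.09 with members at 0 set to the floor. Of these genes 12 belong to other lists as well, such as Cr2 to the B cell list and Ccl21a and Ccl19 to the chemokines, so these medians are not independent of one another. Glycam1, a mucin-like protein of high endothelial venules that the lactating mammary gland also makes, had 4 counts with the PD-1 inhibitor alone and 4923 with acupuncture, 1997-fold higher (779 to 7332). The chemokines that gather T cells and dendritic cells in lymph nodes were 259-fold higher for Ccl21a (175 to 401) and 160-fold higher for Ccl19 (94.8 to 293), and reads of Ccl21a may be shared with its near-identical copies. Of 20 adipocyte genes 19 were higher and none lower, at a median of 2.13 (1.63 to 2.26), and the list took 0.0714% of counts with the PD-1 inhibitor alone and 0.284% with acupuncture. Fabp4, a fatty acid carrier of adipocytes, was 4.87-fold higher (4.78 to 4.95) and the carbonic anhydrase Car3 4.26-fold higher (4.17 to 4.35). Ucp1, the uncoupling protein of brown fat, was 406-fold higher (173 to 1252), and Cidea, a lipid droplet protein abundant in brown fat, was 153-fold higher (80.2 to 335). Of 21 skeletal muscle genes 20 were higher and none lower, at a median of 2.96 (2.66 to 3.76) and with 0.0419% and 0.312% of counts. Fast myosin Myh4 was 32.4-fold higher (31.0 to 33.8), the muscle calcium pump Atp2a1 16.3-fold higher (15.6 to 17.1) and the calcium buffer Pvalb 35.8-fold higher (29.8 to 43.4).

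**Figure D1:**
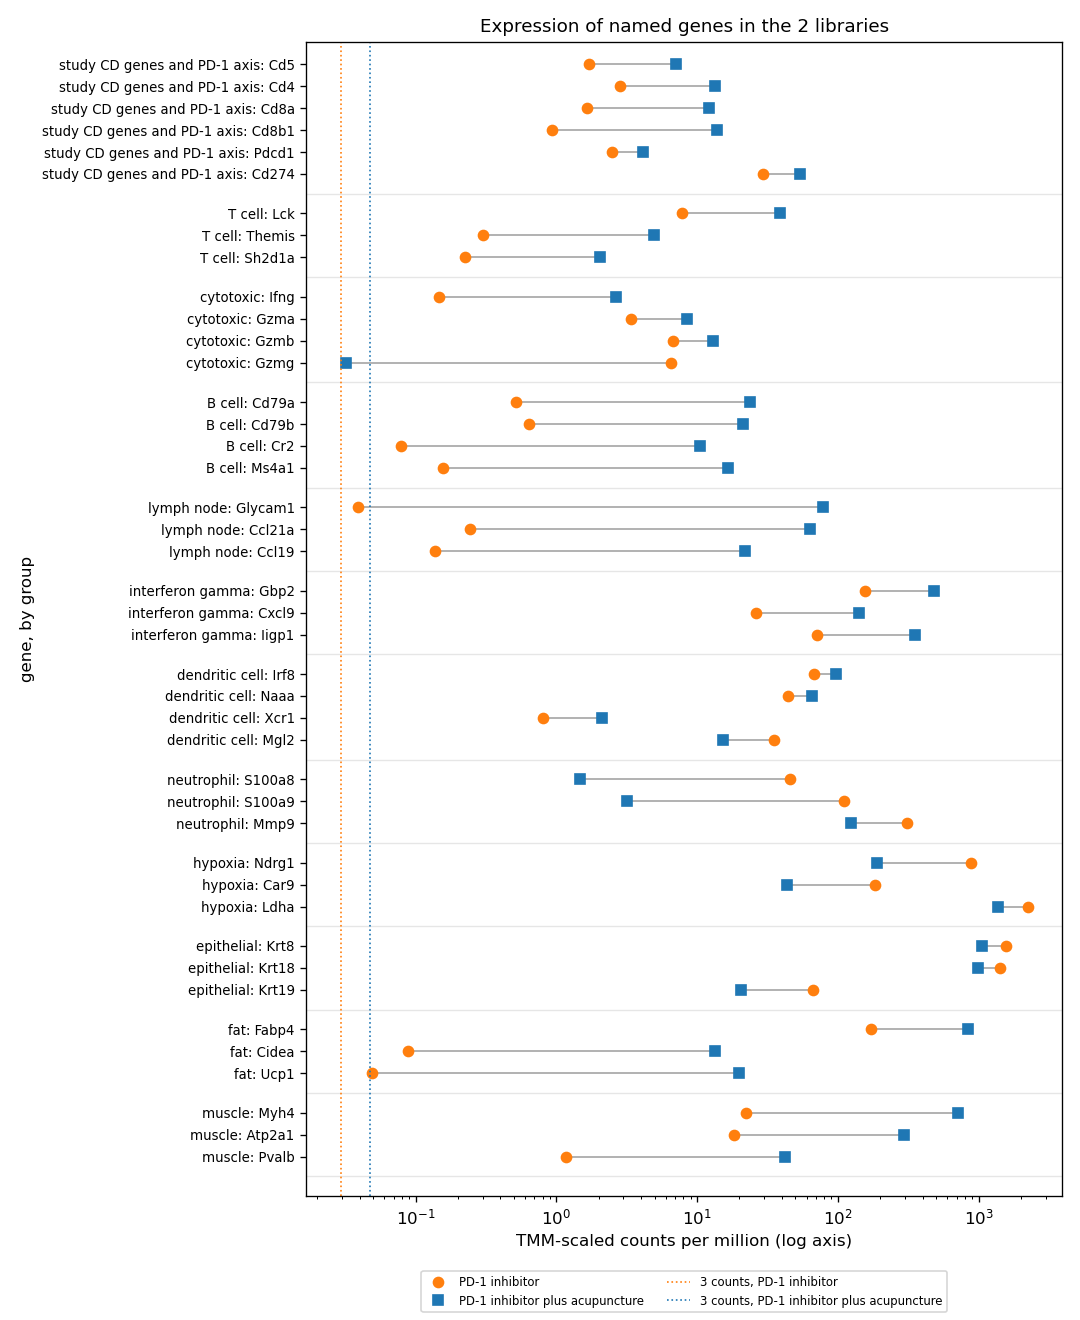
TMM-scaled CPM (log axis) of named genes in the library of the PD-1 inhibitor alone (circles) and with acupuncture (squares), 1 library each, with dotted lines at the level of 3 counts (0.0294 and 0.0477 CPM). Lymphocyte, lymph node, interferon gamma, fat and muscle genes lie further right with acupuncture, except Gzmg, and neutrophil, hypoxia and epithelial genes lie further left.

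Cytotoxic genes went both ways. Of 21 measured, 13 were higher, 4 lower and 4 between, with a median log2 ratio of 1.22 (0.88 to 2.16, above all random lists). Ifng, the cytokine interferon gamma, was 18.1-fold higher (10.6 to 33.0) at 15 and 167 counts. The chemokine Ccl5 was 1.94-fold higher (1.78 to 2.11) and the main cytotoxic granzyme Gzmb 1.92-fold higher (1.73 to 2.12), both between the limits, and both past 2-fold under total count scaling, at log2 ratios of 1.06 for Ccl5 and 1.04 for Gzmb. Of 9 granzymes measured 2 were higher, 5 lower and 2 between, with 3 higher and 5 lower under that scaling. Gzmk was 4.61-fold higher (3.39 to 6.35) and Gzma 2.5-fold higher (2.18 to 2.87), whereas Gzmc was 3.80-fold lower (3.18 to 4.57), Gzmd 8.11-fold lower (6.20 to 10.8), Gzme 2.26-fold lower (1.81 to 2.86) and Gzmf 9.47-fold lower (6.42 to 14.5). Gzmg had 663 counts with the PD-1 inhibitor alone and 2 with acupuncture, 204-fold lower (56.3 to 1691). Gzmd to Gzmg are close copies of one another, so the split of reads among them is uncertain. Of 13 NK cell genes 8 were higher and none lower (median 1.12, 0.18 to 1.68, percentile 99.8), including the receptor Cd160 at 5.23-fold (3.47 to 8.10) and the kinase Txk at 3.56-fold (2.88 to 4.41). Ncam1, among the most abundant of them, stood at 0.956 times its level with the PD-1 inhibitor alone (0.831 to 1.10). Other lists hold 3 of these 13 genes as well, Cd160 among them. Of 18 killer lectin-like receptors 9 were higher and none lower.

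Helper, activation and checkpoint genes were higher in part. Of 14 helper and regulatory T cell genes 6 were higher and none lower (median 0.61, -0.24 to 2.24, percentile 99.8). Cxcr5, the receptor that leads B cells and follicular helper T cells into follicles, was 20.2-fold higher (13.5 to 31.8) at 25 and 312 counts. Its log2 ratio of 4.21 became 5.21 with the deeper library thinned. The CD40 ligand Cd40lg was 13.3-fold higher (5.26 to 43.1). Gata3, which mammary epithelium also expresses, was 1.36-fold lower (1.30 to 1.42). Of 18 activation and co-stimulation genes 11 were higher and 1 lower (median 1.49, 0.34 to 2.48, above all random lists), with the adhesion receptor Cd226 at 8.04-fold (6.11 to 10.7) and the early-response receptor Nr4a1 at 2.69-fold (2.54 to 2.84). Cd44, abundant in many cell types, was 1.47-fold lower (1.45 to 1.49), and the summed counts of that list were lower with acupuncture, at a log2 ratio of -0.26. Of 16 checkpoint genes 5 were higher, none lower and 11 between (median 0.52, -0.29 to 2.09, percentile 99.7), led by Cd96 at 12.9-fold (8.72 to 19.6) and Btla, which B and T cells share, at 6.44-fold (5.46 to 7.62). The more abundant Vsir and Lgals9 stood at 0.816 and 1.01 times their levels with the PD-1 inhibitor alone. The leukocyte list, whose genes are shared by most blood cells, had 2 of 16 higher, none lower and a median of 0.63 (0.04 to 0.83), so the T cell median exceeded it by 1.84 and the B cell median by 4.04. The lymph node, fat and muscle genes given above were higher in the same library as each of these groups.

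Conventional dendritic cell genes differed less than T cell genes. Of 20 measured, 1 was higher, 1 lower and 18 between, with a median log2 ratio of 0.31 (0.13 to 0.57, percentile 98.3), which is 0.32 below the leukocyte list. Xcr1, the chemokine receptor of cross-presenting dendritic cells, was 2.65-fold higher (2.0 to 3.53), the lectin Mgl2 was 2.29-fold lower (2.13 to 2.46), and the transcription factor Irf8 was 1.43-fold higher (1.38 to 1.48). The title of the series places CD5 on dendritic cells, and bulk tissue does not separate the cells that carry Cd5. The log2 ratio of Cd5, 2.03, lay 1.72 above the median of the conventional dendritic cell list (1.48 to 2.0 from the counting interval of Cd5) and 0.47 below the median of the other T cell genes (-0.71 to -0.20). Of 16 migratory dendritic cell genes 5 were higher and 1 lower (median 0.33, -0.07 to 1.34, percentile 98.97), with Il4i1 at 3.30-fold (2.84 to 3.83). Fscn1, the most abundant of them and also made by tumour and stromal cells, was 1.57-fold lower (1.55 to 1.60), and the summed counts of that list had a log2 ratio of -0.24. Of 11 plasmacytoid dendritic cell genes 5 were higher and none lower (median 0.84, -0.24 to 3.07, percentile 99.7), among them Spib, shared with B cells, at 11.8-fold (9.09 to 15.5) and Cox6a2, shared with muscle, at 8.52-fold (7.02 to 10.4).

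Interferon gamma response genes were higher nearly throughout. Of 26 measured, 22 were higher, none lower and 4 between, with a median log2 ratio of 1.67 (1.2 to 1.92, above all random lists). Gbp2, a GTPase of cell-autonomous defence, was 3.08-fold higher (3.02 to 3.14), though its reads may be shared with Gbp2b. Cxcl9, which draws CXCR3-bearing T cells, was 5.42-fold higher (5.19 to 5.67) and the GTPase Iigp1 4.98-fold higher (4.85 to 5.12). Over the family of interferon-induced GTPases 12 of 13 were higher and none lower, and their summed counts were 3.23-fold higher. Of 23 type I interferon response genes 6 were higher and none lower (median 0.83, 0.62 to 0.89, above all random lists), with Ifit3 at 2.56-fold (2.43 to 2.69) and Oasl2 at 1.54-fold (1.5 to 1.57). Antigen presentation genes of MHC class I differed less, with 1 of 17 higher and none lower (median 0.37, 0.26 to 0.64, above all random lists). The peptide transporter Tap1 was 2.07-fold higher (2.02 to 2.11), B2m 1.29-fold higher (1.28 to 1.30) and H2-D1 at 0.938 times its level with the PD-1 inhibitor alone (0.931 to 0.946). Of 12 MHC class II genes 4 were higher and none lower (median 0.79, 0.36 to 2.57, percentile 99.99). The largest ratios there were those of genes typical of B cells, with H2-Ob at 16.8-fold (13.1 to 22.0) and H2-Eb2, at 3 and 52 counts, at 28.1-fold (9.11 to 141), while the invariant chain Cd74 was 1.19-fold higher (1.18 to 1.2). The B cell list, at a median of 4.67, and the lymph node list, at 3.03, were higher in the same library as the interferon gamma genes. Of the MHC genes, 1 of 17 of class I and 4 of 12 of class II were higher there.

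Neutrophil genes were lower with acupuncture. Of 22 measured, 15 were lower, none higher and 7 between, with a median log2 ratio of -1.62 (-3.33 to -0.78, below all random lists). The calcium-binding alarmins S100a9 and S100a8 were 35.2-fold (30.6 to 40.7) and 31.1-fold (25.3 to 38.7) lower, and the matrix metalloproteinase Mmp9 was 2.48-fold lower (2.42 to 2.55). Cxcl3, a neutrophil attractant, was 30.0-fold lower (19.3 to 49.3), while the inflammatory cytokine Il1b was 1.66-fold lower (1.59 to 1.73). Other lists hold 6 of these 22 genes as well, among them Mmp9 (invasion), Cxcl3 (chemokines) and Il1b (interleukins). Macrophage genes had 6 of 22 lower, none higher and a median of -0.39 (-1.02 to -0.24, below all random lists), which became 0.15 with the epithelial list set to a median of 0. Arginase, Arg1, was 4.62-fold lower (4.48 to 4.77), the platelet factor Pf4 3.52-fold lower (3.28 to 3.79) and osteopontin, Spp1, 2.14-fold lower (2.13 to 2.16), though short of 2-fold under total count scaling at a log2 ratio of -0.998, while Apoe was at 0.767 times its level with the PD-1 inhibitor alone. Monocyte genes had 5 of 14 higher and 1 lower (median 0.61, -0.50 to 1.51, above all random lists). Those higher included Ly6c1 at 2.85-fold (2.75 to 2.95), which endothelium shares, and haptoglobin, Hp, at 4.95-fold (4.87 to 5.03), which adipocytes share. Of 11 mast cell genes 1 was higher and 1 lower (median -0.17, -0.68 to 0.11, percentile 8.33). Of 33 chemokines 7 were higher, 8 lower and 18 between, and the median of -0.33 (-0.37 to 0.45, percentile 0.01) and the mean of 0.20 differed in sign, as did the median of 0.21 with the epithelial list set to 0. Of 22 chemokine receptors 10 were higher and 2 lower (median 0.87, 0.05 to 1.38, above all random lists), with the neutrophil receptor Cxcr1, at 47 and 3 counts, 9.66-fold lower (3.11 to 48.5). Of 39 interleukins and growth factors 11 were higher and 4 lower (median 0.30, -0.36 to 0.91, percentile 99.7), and their summed counts had a log2 ratio of -0.05. Il12a, a subunit of interleukin 12, had 0 and 37 counts, at least 20.01-fold higher. Under the main scaling, 15 of 22 neutrophil genes and 6 of 22 macrophage genes were lower with acupuncture. In that same library the fat list (2.13), the muscle list (2.96) and the lymph node list (3.03) had higher medians.

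Genes of hypoxia and glycolysis were lower with acupuncture. Of 27 measured, 12 were lower, none higher and 15 between, with a median log2 ratio of -0.94 (-1.2 to -0.78, below all random lists). The hypoxia markers Ndrg1 and Car9 were 4.68-fold (4.59 to 4.77) and 4.24-fold (4.08 to 4.42) lower. The glycolytic enzymes Pkm and Ldha were 1.74-fold (1.73 to 1.75) and 1.62-fold (1.61 to 1.64) lower. Angiogenic factors had 6 of 22 lower, none higher and a median of -0.31 (-1.06 to 0.06, percentile 0.11), or 0.22 with the epithelial list set to 0, with placental growth factor, Pgf, 3.20-fold lower (2.99 to 3.43) and adrenomedullin, Adm, 3.0-fold lower (2.76 to 3.26). Hif1a stood at 1.04 times its level with the PD-1 inhibitor alone (1.02 to 1.06) and Thbs1 at 0.817 times (0.801 to 0.833). Endothelial genes had 2 of 22 lower, none higher and a median of -0.44 (-0.67 to 0.15, below all random lists), or 0.10 with the epithelial list set to 0. Those lower were Esm1, a marker of sprouting vessels, at 3.83-fold (3.22 to 4.57) and the tight junction protein Cldn5 at 3.12-fold (2.72 to 3.58), while Cd34 was 1.43-fold higher (1.38 to 1.48). Oxidative phosphorylation genes had all 23 members between the limits (median -0.11, -0.31 to 0.03, percentile 35.2).

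Epithelial genes, which mark the tumour cells, were lower by less. Of 23 measured, 5 were lower, none higher and 18 between, with a median log2 ratio of -0.54 (-0.77 to -0.30, below all random lists). The keratins Krt8 and Krt18 were 1.48-fold (1.46 to 1.49) and 1.45-fold (1.44 to 1.46) lower, Krt19 was 3.28-fold lower (3.09 to 3.48), and Krt5 was 6.41-fold lower (3.35 to 13.8) at 104 and 10 counts. Of 10 genes of mammary secretory epithelium 1 was higher, which was Glycam1, and 4 were lower (median -0.54, -3.36 to 0.04, percentile 0.72), and the median was 0.03 among those with a combined count of at least 100. Elf5, which directs alveolar differentiation, had 53 and 0 counts, at least 10.9-fold lower. Of 24 genes of epithelial-mesenchymal transition and invasion 5 were lower and 2 higher (median -0.62, -0.77 to -0.13, below all random lists), with the matrix metalloproteinases Mmp10 and Mmp13 3.57-fold (3.24 to 3.95) and 2.59-fold (2.49 to 2.70) lower. Vim was 1.36-fold lower (1.35 to 1.37) and fibronectin, Fn1, 1.63-fold lower (1.62 to 1.63). All 32 proliferation genes lay between the limits, with a median of 0.16 (0.05 to 0.22, percentile 99.99), and the cycle markers Top2a and Mki67 were 1.14-fold (1.12 to 1.15) and 1.09-fold (1.08 to 1.11) higher. Of 27 pro-apoptotic genes 1 was higher, none was lower and 26 lay between (median 0.08, -0.15 to 0.46, percentile 88.9). That gene was the death ligand Tnfsf10 at 2.47-fold (2.30 to 2.65). All 12 anti-apoptotic genes lay between the limits (median -0.13, -0.45 to 0.07, percentile 20.4), among them Bcl2l1, 1.53-fold lower (1.48 to 1.58). The fat, muscle and lymph node genes given above were higher in the same library in which epithelial and hypoxia genes were lower.

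Fibroblast and matrix genes had 2 of 25 higher and none lower (median 0.17, -0.17 to 0.63, percentile 99.98), with Col3a1 at 1.57-fold (1.57 to 1.58) and the stromal protease Fap at 2.34-fold (2.16 to 2.52). Pericyte and smooth muscle genes had 4 of 16 higher and none lower (median -0.10, -0.36 to 1.05, percentile 18.0), and the largest ratio was that of desmin, Des, which skeletal muscle shares, at 3.41-fold (3.27 to 3.56). Of 20 unfolded protein response genes 1 was higher and 19 lay between (median -0.09, -0.20 to 0.21, percentile 42.3), a median that was 0.01 when the libraries were scaled to total counts. Of 19 immediate early and heat shock genes 2 were higher and 4 lower, with a median of 0.10 (-0.98 to 0.24, percentile 97.6) and a mean of -0.27, which differ in sign, and summed counts at a log2 ratio of -0.07. The inducible heat shock protein Hspa1a was 5.49-fold lower (4.99 to 6.04) and the early-response gene Ier3 4.38-fold lower (4.20 to 4.57). Of 9 erythroid genes 5 were higher and none lower (median 1.05, -0.17 to 1.42, percentile 99.99), with the globin Hbb-bs at 2.58-fold (2.52 to 2.65). Of 16 nerve and Schwann cell genes 7 were higher and 1 lower (median 0.70, -0.01 to 1.09, percentile 99.9). Of 8 skin genes measured 2 were higher and 2 lower (median -0.05, -2.29 to 1.77, percentile 27.2), and this median was 0.05 under total count scaling. Cytosolic ribosomal proteins took 7.03% of counts with the PD-1 inhibitor alone and 5.59% with acupuncture, with 7 of 99 lower and 1 higher, and their median log2 ratio of -0.43 became 0.11 with the epithelial list set to 0. The 13 mitochondrially encoded genes took 1.85% and 2.68%, with 12 between the limits and 1 lower. Of 12 S100 genes 4 were lower and none higher, of 22 keratins 6 were lower and 2 higher, of 41 collagens 5 were lower and 4 higher, and of 67 histone genes 1 was lower and 1 higher. With the epithelial list set to 0, the numbers lower and higher were 1 and 2 for ribosomal proteins, 0 and 5 for mitochondrially encoded genes, 3 and 8 for collagens and 0 and 8 for histones.

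**Figure D2:**
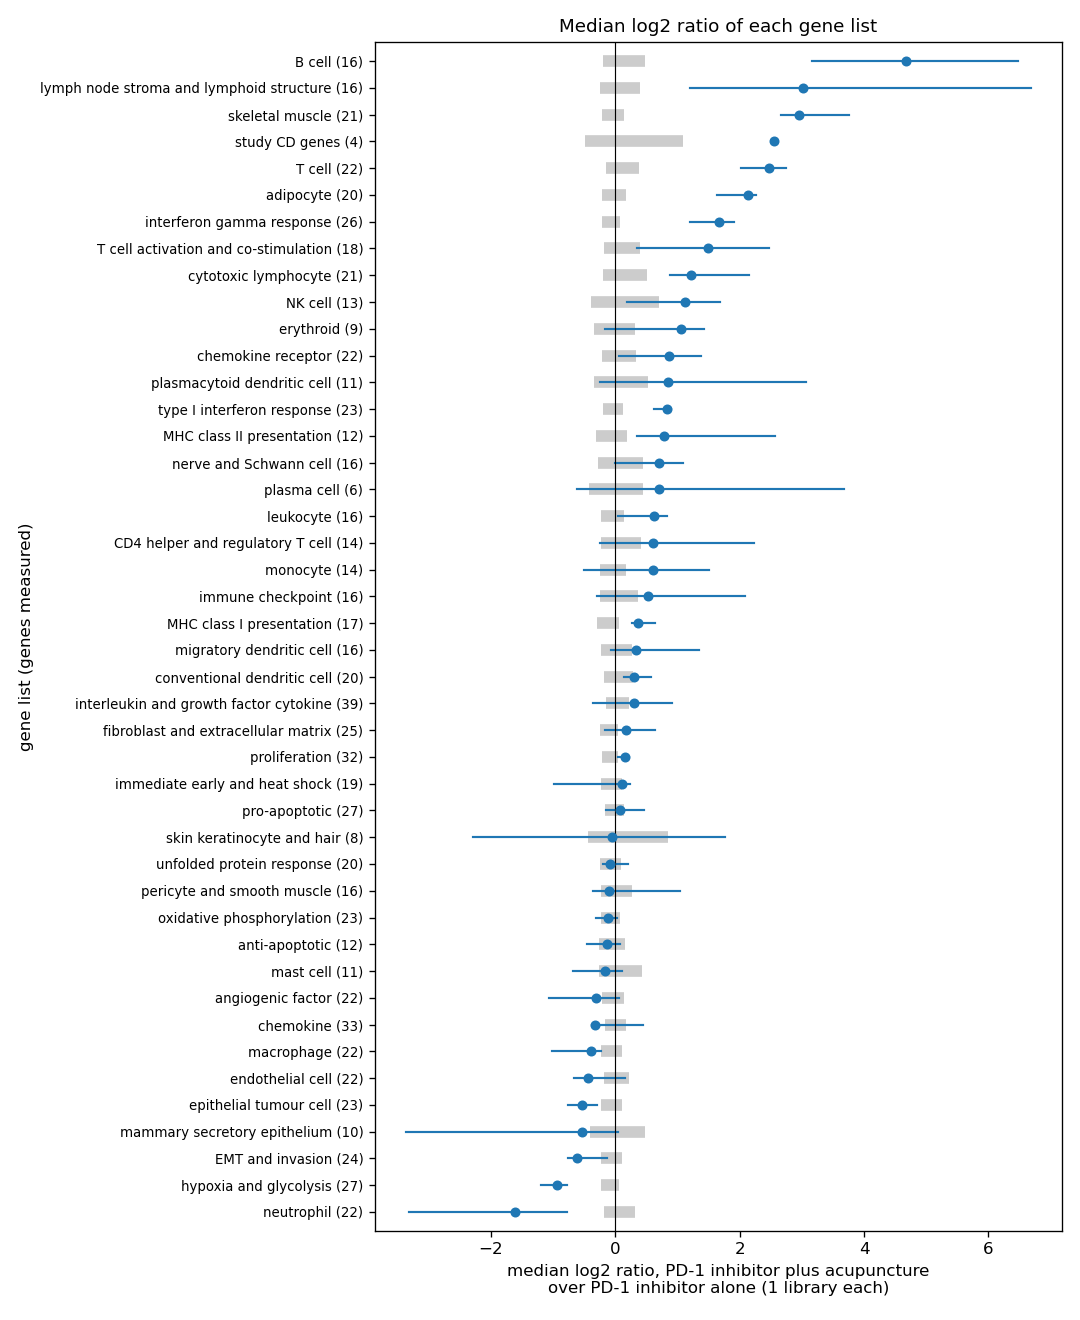
Median log2 ratio (PD-1 inhibitor plus acupuncture over PD-1 inhibitor alone, 1 library each) of the 44 gene lists, with the number of genes measured beside each name; dots are medians, blue lines 95% binomial intervals of the median over genes, and grey bars the range that holds 95% of 10000 expression-matched random lists. The B cell list lies furthest right at 4.67 and the neutrophil list furthest left at -1.62.

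Across the 18687 genes with a combined count of at least 20, 1721 (9.21%) were at least 2-fold higher with acupuncture with a counting interval that excluded 1, 916 (4.90%) were at least 2-fold lower and 16050 lay between. Of the listed genes 65.3% were higher. With the epithelial list set to a median of 0, a scaling chosen after the data were seen, 3543 genes were higher and 359 lower, so that 90.8% were higher. Among 11323 genes with a combined count of at least 1000, 346 were higher and 199 lower. The 10 genes with the highest ratios were Glycam1, Ucp1, Fcmr, Ccl21a, Ccl19, Cidea, Cr2 and the B cell antigen Ms4a1, 105-fold higher (64.4 to 184), with Marco, a scavenger receptor of macrophages, at least 88.7-fold higher from 0 and 164 counts and the imprinted transcript Peg13 at least 85.5-fold higher from 0 and 158 counts. The 10 with the lowest ratios included Gzmg, S100a9, S100a8 and Cxcl3. The cystatins Stfa2, at 153 and 0 counts, and Cstdc4 were at least 31.4-fold and 16.3-fold (10.6 to 26.5) lower, with reads that may be shared among close copies. Also among them were the mucus-associated protein gene Fcgbp, 40.1-fold lower (20.2 to 93.3), Prn, 34.7-fold lower (13.4 to 128), and the noncoding RNA Lncppara, 25.5-fold lower (14.1 to 51.5). The 10 most abundant genes took 4.65% of counts with the PD-1 inhibitor alone, led by Eef1a1, COX1, Fn1 and Spp1, and 4.78% with acupuncture, led by COX1, Eef1a1, Col3a1 and CYTB.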

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

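Of the alternatives given here, thinning of the deeper library and scaling to the epithelial list were chosen after the data were seen, and the others before the data were examined. No paired analysis was possible because each group had 1 library and no replicate number was shared. Scaling by total counts moved log2 ratios by up to 0.10, as did totals without the 10 most abundant genes, and DESeq2 and upper-quartile scaling by up to -0.0003 and 0.02, with smaller shifts for genes with few counts because of the prior count. The numbers of genes higher and lower were 1055 and 500 with a combined count of at least 100 and 678 and 262 at a 4-fold limit, both by construction, since fewer genes can pass. They were 3543 and 359 with the epithelial list set to a median of 0, which raises every log2 ratio, and those of genes with few counts by less. That scaling gave log2 ratios of 2.56 for Cd5, 2.77 for Cd4 and 3.40 for Cd8a, and list medians of 2.995 (T cell), 0.84 (conventional dendritic cell), 2.21 (interferon gamma response) and -0.40 (hypoxia and glycolysis). It reversed the medians of the macrophage (0.15), chemokine (0.21), endothelial (0.10) and angiogenic (0.22) lists. Ratios of summed counts, which the most abundant members set, gave 1.03 for the T cell list, where Thy1 is the most abundant member, and reversed the T cell activation (-0.26), plasma cell (-0.20), migratory dendritic cell (-0.24), interleukin (-0.048) and immediate early (-0.073) lists. Means reversed the chemokine (0.20) and immediate early (-0.27) lists. With a combined count of at least 100 the mammary secretory median became 0.032, from fewer genes. Over all comparisons, those above included, 486 values of the 44 list medians stayed within their intervals, 29 moved and 12 reversed, with other changes of sign only in lists whose median lay within the range of the random lists, and of the 180 named genes 1078 values stayed and 362 moved, most under the scalings with the largest shifts. Depth limits genes near 3 counts, and the library with acupuncture has the higher floor.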

Other observations

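The tests of effector T cells alone, of scaling and of lymphoid tissue for the interferon gamma genes, and of dilution for the neutrophil and hypoxia genes were chosen after the result was seen, and so were the abundant and clock genes named here and the division of the brown fat genes. Among 1768 genes with a combined count of at least 20000, 23 were higher and 37 lower with acupuncture, of which 3 and 21 lay outside the fixed lists. The 10 lowest of these 21 were H19, Slpi, Hmox1, Malat1, Saa3, Mt2, Mt1, Ddit4, Tnnt2 and Timp1. H19, an imprinted noncoding RNA active in the embryo, was 5.02-fold lower (4.93 to 5.1), the protease inhibitor Slpi 4.18-fold lower (4.1 to 4.26), heme oxygenase Hmox1 4.12-fold lower (3.99 to 4.27) and the nuclear noncoding RNA Malat1 3.44-fold lower (3.38 to 3.51). The others ranged from 3.32-fold lower for serum amyloid Saa3 (3.2 to 3.45) to 2.47-fold lower for the metalloproteinase inhibitor Timp1 (2.4 to 2.55). Also among the 21 were the ribosomal protein genes Rps29, Rps28, Rpl38 and Rpl37a, the mitochondrially encoded ND6, and AY036118. These ranged from 2.30-fold lower for Rps29 (2.24 to 2.35) to 2.11-fold lower for Rpl37a (2.08 to 2.15). The 3 higher genes were Scd1, a desaturase of fat synthesis, at 4.15-fold (4.1 to 4.2), the stem cell and leukocyte antigen Ly6a at 2.56-fold (2.52 to 2.61) and the fibrillar-collagen partner Col14a1 at 2.34-fold (2.27 to 2.4). Across 14342 genes with a transcript in GENCODE M21 on GRCm38, which are not independent replicates, the median log2 ratio was -0.27 for the 787 genes under 1 kb and 0.03 for the 8062 over 3 kb, and Spearman's rho of the log2 ratio was 0.12 with transcript length and -0.30 with GC content. Removing the trend with length and GC content, a fit with an R squared of 0.033, moved the ribosomal protein median from -0.44 to -0.43.

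Some genes of the circadian clock were looked at after their values were seen, with no fixed list and no count over the clock as a whole. Cry1, Dbp and Per2 were 2.1-fold (1.91 to 2.31), 2.1-fold (1.94 to 2.27) and 2.05-fold (1.9 to 2.22) higher with acupuncture, and Npas2 stood at 0.406 times (0.256 to 0.623) its level with the PD-1 inhibitor alone. Arntl, at 0.566 times (0.505 to 0.633), Per3, at 1.81 times (1.71 to 1.92), Nr1d1, at 0.792 times, and Per1, at 1.11 times, lay between the limits.

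The T cell genes, Cd5 among them, were higher in a library in which the lists of lymphoid structure, fat and muscle genes also had higher medians. With the deeper library thinned the T cell median was 2.44. This bears on depth only through the count filter and the prior count, because random thinning keeps the expected ratios. Lymphoid tissue in the piece sampled is a candidate explanation. It could come from a node next to the mammary gland or from lymphoid structures formed in the tumour. Genes of resting T and B cells outside the fixed lists had a median log2 ratio of 2.19 (0.43 to 3.50). Of these 13 genes 8 were higher, and the most different members, Dapl1 and Vpreb3, went from 0 counts to 74 and 40. More T and B cells from any source would raise these genes, so they cannot tell lymphoid tissue from recruited cells. Effector T cell genes had a median of 0.91 (0.40 to 3.97), an interval too wide to decide. Genes of lymph node vessel, reticular and sinus cells had a median of 0.31 (-0.53 to 2.14), also too wide. Among these last 10 genes 3 were higher, led by Stab2 at 11.3-fold, and 7 lay between the limits, down to Clu at 0.608 times. With the PD-1 inhibitor alone Clu was at 701 CPM and Stab2 at 0.186. Genes already abundant in that library could report little of added node cells. Recruitment of T cells by acupuncture stays open and untested, because treatment and tissue content are confounded with 1 library per group.

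Interferon gamma response genes kept a median of 1.47 after a fitted trend of log2 ratio on transcript length and GC content was removed. That fit had an R squared of 0.033, so a small change was likely whatever the cause. It does not decide whether length or GC content contributed. The planned scalings moved log2 ratios by at most 0.10 and so decided nothing, but a wrong scaling would shift matched random lists as well, and the lower end of the list's interval lay 1.13 above their range. All 26 members of the list had a length and a GC content. The list gained 12.1 times the CPM gained by the leukocyte list, but without a profile of lymphoid tissue this cannot be told apart from interferon-exposed cells brought in with such tissue. A response of tumour and stromal cells to more interferon gamma, whose gene Ifng was 18.1-fold higher, was not separated from that. Bulk tissue does not tell the cells apart, and an effect of acupuncture stays untested without replicates.

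Neutrophil and hypoxia genes were both lower in the acupuncture library. Dilution of the tumour by tissue that lacks epithelial genes would lower them no more than epithelial genes. Added tissue with epithelial genes of its own could spare that list, and the comparison cannot decide on such dilution. Their medians lay 1.09 and 0.40 below the epithelial median (differences of -1.09 and -0.40). Their intervals ended just short of that of the epithelial list (upper ends of -0.78 for both, against a lower end of -0.77). Genes of 1 list are not independent, so a gap this narrow does not decide on dilution. Removing the fitted length and GC trend left the hypoxia median at -1.01, but with an R squared of 0.033 that fit decides nothing here. Sampling of another region, such as the margin in place of a necrotic, hypoxic core where neutrophils gather, may account for both and was not tested, and an effect of acupuncture stays open as well.

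Brown fat in the piece sampled is a candidate source of Ucp1 and Cidea, a hypothesis whose test was set before its result was seen: 9 brown fat genes outside the fixed lists, 8 of them higher, had a median of 2.80 (2.20 to 3.20), against 2.13 for the adipocyte list. Of these, Cox8b, Cox7a1, Cpt1b and Ppargc1a are the 4 best known from skeletal muscle, whose list had a median of 2.96. Muscle is therefore an alternative source of part of this. The 5 others, which were not checked for expression in muscle, had a median of 2.80 with no interval from so few genes. They ranged from Elovl3 at 0 and 40 counts to Dio2, which went the other way at 0.667 times (0.619 to 0.718).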
